A study of Mus musculus with 16 samples.

How the data were processed

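RNA was measured by sequencing in mouse E14 embryonic stem cells with the genotype label Tip60-H3F. The labels divide 16 libraries into 8 groups of 2, a control group and a group overexpressing RNaseH1 at each of days 0, 2, 4 and 10 of differentiation. Cells grew without feeders on gelatin in serum and LIF. Differentiation was started by withdrawing LIF, with 2 days in suspension before plating on gelatin. Total RNA was extracted with TRIzol, depleted of ribosomal RNA, primed at random and made into stranded libraries by the dUTP method with 16 cycles of PCR. The labels do not say whether the 2 libraries of a group came from separate cultures.

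Per the submitters' processing notes, the authors used CASAVA 1.8.2, Bowtie2 2.1.0, RSEM and DESeq2 with the mouse build mm9. The submitters' notes do not state the role or order of these tools, the version of DESeq2 or whether fold changes were shrunken. The deposited files were 4 DESeq2 comparison tables made by the authors, 1 per day, with RefSeq transcript accessions as row labels and no value for any single library. The signal column, per the file headers the base mean, is the authors' mean of size-factor normalised counts over the 4 libraries of a day. The authors' log2 columns hold the fold change between the groups and its standard error. The authors' score column is the Wald statistic, which equalled their ratio. The deposited p-value columns hold the Wald test p and its Benjamini-Hochberg adjusted value, which is missing below a base mean of 12.2, 90.9 and 176 on days 0, 2 and 4. The headers give no direction, so it was set as RNaseH1 over control from the row labelled Rnaseh1, whose fold change was positive in all 4 tables. No depth per library is given, so precision is known only through the authors' standard errors. The largest of these were 0.49, 0.34, 0.33 and 0.70 on days 0, 2, 4 and 10. Rows occurred with base means of 3.52, 3.38, 3.95 and 2.51 on those days. Counting noise alone would give such rows larger errors, which argues that the fold changes were shrunken, by an amount that is not known. If the libraries of a group shared a culture, the p-values measure technical spread alone.

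Symbols were taken from a RefSeq table on the assembly GRCm38.p6, which named 18200 of the 18424 labels. That assembly is not the build of the files, so no coordinates are printed. Row labels were checked against levels. Labels of genes transcribed in every cell type or abundant in stem cells served as anchors, and labels of genes silent in such cells served as their opposite. A stretch of rows counted as checked where at least 15 anchors in a row of the accession order each had a mean base mean of at least 300, trimmed at its ends to anchors that were not exceeded by their neighbours within 3 rows. Outside that stretch, anchors were read at their own row and up to 3 rows to each side. The anchor classes, the stretch rule and the division of the other rows into lower, middle and upper accession blocks were chosen and adjusted after values had been seen. Because the stretch was chosen by its anchors, their share at the minimum there is fixed by the rule.

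The tests, the lists and the rule for named genes were fixed before the data were examined. For each day, rows with an adjusted p under 0.05 in the authors' deposited table were counted as called. In the counts by list, rows without an adjusted p were counted as not called, so these counts are not alike between days. The named genes were Rnaseh1, the 6 highest and 6 lowest log2 fold changes among called rows with a base mean of at least 50, up to 3 called members of each list with the smallest adjusted p, and 10 genes named whatever their result. Restricting names to the checked stretch was decided after the label check. Of the 10 genes always named, Nanog, Fgf5 and Sox17 lay in it, and Pou5f1, Sox2, Zfp42, T, Gata6, Pax6 and Nes did not, so no effect is given for those.

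There were 23 lists: pluripotency, primed epiblast, primitive streak and early mesoderm, endoderm, neuroectoderm, cardiac muscle, endothelium and blood, trophoblast, mesenchyme and matrix, Hox genes, developmental transcription factors with Polycomb-marked promoters, Polycomb subunits, Tip60-p400 subunits, R-loop processing without Rnaseh1, p53 targets, interferon response, 2-cell-like state, replication-dependent histones, ribosomal proteins, glycolysis and hypoxia, immediate early, proliferation and imprinted genes. Each was tested with cameraPR of limma 3.58.1 on the Wald statistic with an inter-gene correlation of 0.01, two-sided, with at least 3 members and Benjamini-Hochberg adjustment over lists and days. An inter-gene correlation cannot be estimated without values per library, and 0.05 was used as the alternative.

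Effects of 2 days were compared by the difference of their log2 fold changes over the root of the summed squared standard errors, a two-sided z test adjusted over rows, for 4 pairs of days. Days shared no libraries. The 5 highest and 5 lowest z among called rows of the checked stretch with a base mean of at least 50 were named. Agreement between days was described by correlations across rows with a base mean of at least 50 and by overlaps of called rows with Fisher's exact test, two-sided. Levels over the course were base means per 1000000 of the summed base means of a table, without a test.

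Alternatives fixed in advance were other thresholds (adjusted p under 0.01 or 0.1, at least 2-fold), other filters (none, base mean of at least 10, 50 or 200), an empirical null that recentred and rescaled the statistic, cameraPR on fold changes or ranks, and another scaling between days. Alternatives chosen after seeing the data were a dispersion of 0.01 or 0.04 added to each squared error, the list differences on fold changes, on ranks, with a correlation of 0.05 and with a base mean of at least 10, the lists with label-checked rows only, and a displaced reading that takes a label's value 1 row below it in the middle block and on its own row in the checked stretch. A version of that reading that also moved the upper block was tried first and dropped. The replicate block, leaving out replicates and another normalization were planned but need values per library.

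The steps were tested on simulated data. With 15951 rows, the difference test recovered 89.0% of changes of 1 log2 unit and 47.0% of changes of 0.5, with 5 false calls among 141. The label check found a simulated displacement and none where there was none. The cameraPR step found a shifted list and called 10 of 200 null lists at an unadjusted p under 0.05. The simulated effects were drawn from the authors' standard errors, anchor levels were set above the minimum, and list statistics were independent. These simulations therefore check the code and not the error rates in the data. In the data the z of days 10 and 0 spread more widely, with an empirical null width of 3.04. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3.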

Results

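Total RNA was profiled in mouse E14 embryonic stem cells, with and without overexpression of RNaseH1, an enzyme that degrades the RNA strand of RNA:DNA hybrids. The 16 libraries formed 8 groups of 2, control and RNaseH1 at days 0, 2, 4 and 10 after the start of differentiation by LIF withdrawal. The comparisons ask how removal of such hybrids, which form R-loops near promoters, alters transcript levels in stem cells and in their differentiating progeny. No value or depth per library was given. The base means, which are normalised read counts averaged over the 4 libraries of a day, summed to 14494863, 13066017, 13795617 and 14145482 at days 0, 2, 4 and 10 in the authors' deposited tables.

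Most row labels could not be taken at face value. In the authors' deposited tables, averaged over days, the row labelled Eef1a1, the abundant translation elongation factor, had a base mean of 35.9 and the next row 217932. The row labelled Sox2 held 9.54 and the next 4458, and the row labelled Zfp42 held 111 and the next 8208. In the middle accession block, 66.0% of 388 labels of housekeeping or abundant genes had a base mean of at least 300 on their own row and 93.0% had it 1 row below. For the 64 ribosomal protein labels of that block the median base mean was 645 on the own row and 13745 on the next. In the upper block, 51.3% of 78 such labels reached the minimum on their own row and 84.6% did so 2 rows below. For such labels the lower block showed no single best row, with 69.2% of 91 on the own row and 65.9% 2 rows below. Its 110 labels of silent genes were lowest on the own row, where 15.5% reached the minimum, against 22.7% to 35.5% on the other rows read.

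By their anchors, labels and levels went together in 1 stretch of 689 accessions, from Prpf19 (NM_001253843) to Flna (NM_001290421), and genes are named from that stretch alone. It held 20 anchor labels, all at or above the minimum by the way the stretch was chosen, and 13 of them were the highest within 3 rows. None of the 8 labels of silent genes in it reached the minimum, a count that the choice did not fix. With 20 anchors over 689 rows, a displacement of a few rows inside the stretch would be missed. The row labelled Adarb2, in the stretch, had base means of 9673, 14440, 6595 and 3770 at days 0, 2, 4 and 10. These levels are out of keeping with that name. Counts over all rows of a single day do not depend on labels. Comparisons between days match rows by label, so they need the same displacement on all 4 days. For the 64 ribosomal protein labels of the middle block, the daily median base mean was 538 to 601 on the own row. It was 10613 to 20318 on the next row and 861 to 1112 on the row after. Other rows were not checked day by day.

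**Figure D1:**
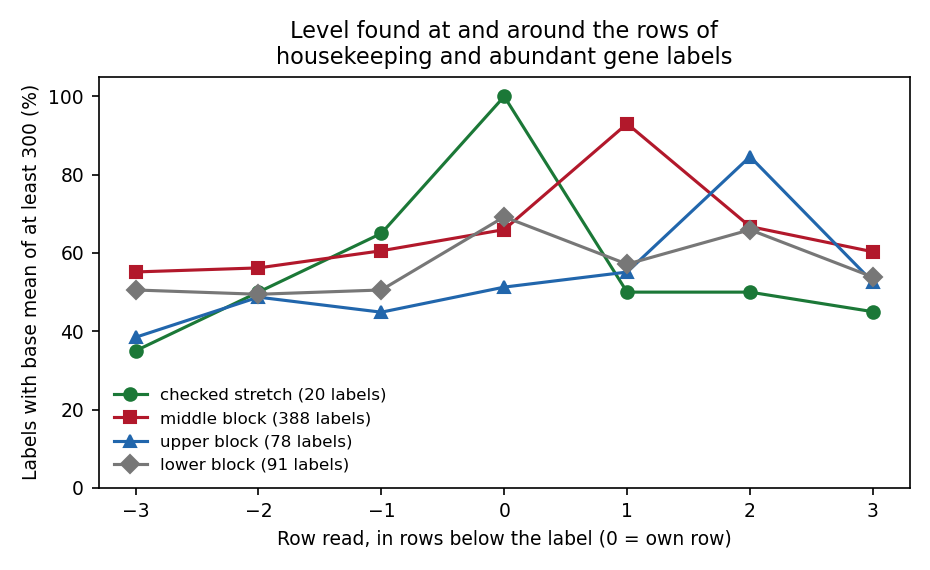
Percent of labels of housekeeping and abundant genes with a base mean of at least 300 (y axis) at the row read, in rows below the label (x axis, 0 is the label's own row), for each block of accessions. The middle block goes from 66.0% on the own row to 93.0% 1 row below, and the checked stretch is at 100% on its own row because it was chosen so.

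Rnaseh1 (NM_001286865), the overexpressed gene, was raised on every day. Its log2 fold change was 2.61, 1.64, 2.06 and 1.99 at days 0, 2, 4 and 10, with standard errors of 0.08, 0.09, 0.10 and 0.11 in the authors' deposited tables. Ranked by the lowest fold change over the 4 days, it stood at rank 1 of 10219 rows, and the next row reached 0.63. The headers state no direction, and this row sets the sign used throughout.

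In undifferentiated cells at day 0, replication-dependent histone transcripts rose together. Of the 60 rows with such labels, 47 were higher with RNaseH1, 2 were lower and 11 were not called, and the counts adjusted over the list alone were also 47 and 2. Their median log2 fold change in the authors' deposited table was 0.92, against 0.01 over all rows (cameraPR adjusted p = 2.2e-135). H2bc4 (NM_001290380), a histone H2B gene of the checked stretch, had a log2 fold change of 1.12 with a standard error of 0.02 in the authors' deposited table. Only 1 histone label lies in the checked stretch, but 72.6% of them have another histone label 1 row below and 66.1% have one 2 rows below. With each value of the middle block given to the label 1 row above it, a reading chosen after seeing the data, 11 histone rows remained. Their median was 1.00, 0.09 and 0.14 at days 0, 2 and 4 (adjusted p = 2.6e-66, 0.0014 and 4.8e-08), against 0.92, 0.22 and 0.24 with the labels as deposited.

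Among the other named rows of day 0, Gm10408 (NM_001256501) had the highest log2 fold change of the checked stretch, 4.35 with a standard error of 0.25 in the authors' deposited table. Crabp1, a retinoic acid binding protein, rose by 1.19 (standard error 0.11), and D630023F18Rik, Gm44504 and Csf2rb2 by 1.67, 1.70 and 1.48 in the authors' deposited table. The lowest were Ephx2 (NM_001271402), a soluble epoxide hydrolase, at -1.58 (standard error 0.06), Trim2 at -1.39, Lamb3, a laminin chain, at -1.29, Zmat4 at -1.27, Mcf2 at -1.24 and Gm21304 at -1.12 in the authors' deposited table. Of the 3 pluripotency labels of the stretch 2 rose at day 0 and 1 was not called, also when adjusted over the list alone. Nanog (NM_001289828), a core pluripotency factor, and Tcl1 each had a log2 fold change of 0.21 in the authors' deposited table (standard errors 0.03 and 0.05), and Tet1, a 5-methylcytosine dioxygenase, had 0.07 with an adjusted p of 0.14. Otx2, a factor of the primed epiblast, rose by 0.43 and Mdm2, a p53 target and regulator, by 0.44, while fibronectin (Fn1) was lower at -0.47 and Mtf2, a Polycomb-associated protein, at -0.18 in the authors' deposited table. Of the ribosomal protein labels of the stretch, Rpl37rt rose by 0.46 and Rpl22 by 0.18, and Gapdh, a glycolytic enzyme, was lower at -0.19 in the authors' deposited table.

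Over all rows of day 0, 5690 of 13776 with an adjusted p were called by DESeq2 in the authors' deposited table, 2691 higher and 2999 lower. Of these, 521 differed at least 2-fold, 352 higher and 169 lower. In the checked stretch 193 of the 513 rows with an adjusted p were called. With the empirical null 1079 rows passed, 595 higher and 484 lower, and the calls of Gm44504, D630023F18Rik, Csf2rb2, Lamb3, Tcl1, Otx2, Mtf2 and Rpl22 ended.

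At day 2 of differentiation the fold changes as deposited were smaller. At base means of 1000 to 5000 their SD was 0.20 against 0.37 at day 0. With the most shrinkage that the largest standard errors allow undone, it was 0.21 against 0.38. At base means of 50 to 200 the SD was then 1.18 against 0.67 and the interquartile range 0.54 against 0.73, so at such levels the order is not settled. Fn1 was lower at -0.89 with a standard error of 0.05, next to Ncor2, a nuclear receptor corepressor, at -1.02 and Brd4, a bromodomain protein, at -0.81 in the authors' deposited table. The latter 2 rows changed sign between days. Ncor2 was at 0.98, 0.05 and 0.94 and Brd4 at 0.76, -0.02 and 0.12 on days 0, 4 and 10. Zdbf2, an imprinted gene, stood at -0.82, Rora at -0.73 and Cnot6l at -0.66 in the authors' deposited table. The highest rows after Rnaseh1 were Aire (0.63), Stk16 (0.61), Arc (0.57), Cndp2 (0.49) and Slc4a2 (0.48) in the authors' deposited table. Tet1 was the 1 of 3 pluripotency labels that fell, at -0.50 (1 higher and 1 lower adjusted over the list alone), in the authors' deposited table. Of the 4 primed epiblast labels 3 fell and 1 rose, also adjusted over the list alone, with Lef1 at -0.26, Fgf5 at -0.19 and Dnmt3a, a DNA methyltransferase, at -0.12 in the authors' deposited table. Nanog was at -0.04 with an adjusted p of 0.76, and Sox17, an endoderm factor, was at -0.03 at a base mean of 11.4 in the authors' deposited table. Mtf2 (-0.15) and Gapdh (-0.14) were lower and Mdm2 (0.30) and H2bc4 (0.19) higher in the authors' deposited table. Of 61 histone rows 33 rose, 1 fell and 27 were not called, and 36 rose and 2 fell adjusted over the list alone (median log2 fold change 0.22 in the authors' deposited table, cameraPR adjusted p = 3.4e-32). Some of the 27 lay below the base mean of 90.9 and had no adjusted p.

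Over all rows of day 2, 2253 of 9737 with an adjusted p were called by DESeq2 in the authors' deposited table, 1136 higher and 1117 lower. At least 2-fold changes were 19, with 5 higher and 14 lower. In the checked stretch 84 of the 357 rows with an adjusted p were called. With the empirical null 839 rows passed, 417 higher and 422 lower, and the calls of Aire, Arc, Slc4a2, Rora, Cnot6l, Fgf5, Lef1 and Mtf2 ended.

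Day 4 gave the smallest fold changes as deposited, with a median size of called rows of 0.25 against 0.28 at day 2. With the most shrinkage that the largest standard errors allow undone, the order of these 2 days was not settled. At base means of 1000 to 5000 the SD was then 0.19 at day 4 against 0.21 at day 2. The interquartile range was 0.26 against 0.23. After Rnaseh1 the highest rows were Gm10408 at 0.83, Acta1, the skeletal muscle actin, at 0.76, Wnt5b, a Wnt ligand, at 0.56, Adarb2 at 0.53 and Arc at 0.49 in the authors' deposited table. The lowest were Cnot6l at -0.59, the GTPase Rab18 at -0.56, Egflam at -0.46, Wnk3 at -0.37, Sass6 at -0.36 and Zmym6 at -0.35 in the authors' deposited table. Of the primed epiblast labels 2 of 4 fell, Fgf5 at -0.33 (standard error 0.05) and Otx2 at -0.23, and of the pluripotency labels 1 of 3, Tet1 at -0.20, with the same counts adjusted over the list alone, in the authors' deposited table. Mtf2 was lower at -0.22 in the authors' deposited table. Nanog (0.00, adjusted p = 0.98) and Sox17 (-0.15, adjusted p = 0.17) were not called in the authors' deposited table. H2bc4 rose by 0.39 and Rpl37rt by 0.26, and of 61 histone rows 33 rose, none fell and 28 were not called in the authors' deposited table. Many of the 28 lay below the base mean of 176 and had no adjusted p. Adjusted over the list alone 35 rose, and the histone median was 0.24 (cameraPR adjusted p = 1.8e-55).

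Over all rows of day 4, 2726 of 9115 with an adjusted p were called by DESeq2 in the authors' deposited table, 1329 higher and 1397 lower, and 3 of them, all higher, differed at least 2-fold. In the checked stretch 101 of the 332 rows with an adjusted p were called. With the empirical null 641 rows passed, 325 higher and 316 lower, and the calls of Wnt5b, Arc, Egflam, Sass6, Zmym6, Tet1, Otx2 and Mtf2 ended. The row labelled Adarb2, a brain protein related to RNA editing enzymes, had a base mean of 6595 at day 4 in the authors' deposited table. That level is out of keeping with the name, and labels of the stretch were not checked singly.

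At day 10 the pluripotency labels of the checked stretch were lower with RNaseH1 than in controls, and so were 2 of the 4 primed epiblast labels. All 3 pluripotency labels of the checked stretch were lower, Tcl1 at -1.89 (standard error 0.15), Nanog at -1.68 (0.06) and Tet1 at -1.33 (0.06) in the authors' deposited table, and the count adjusted over the list alone was also 3. Of the 4 primed epiblast labels, Fgf5 at -2.56 (0.13) and Otx2 at -2.06 (0.07) fell and Lef1 (0.48) and Dnmt3a (0.11) rose in the authors' deposited table, with the same counts adjusted over the list alone. Dnmt3a was named after its value was seen, and with the empirical null neither rise passed (adjusted p = 0.91 for Lef1 and 1.00 for Dnmt3a), while Fgf5, Otx2 and the 3 pluripotency rows did. Mtf2 was lower at -1.22 (0.05) and Brd8, a subunit of the Tip60-p400 complex, at -0.49 (0.05) in the authors' deposited table. Tested on label-checked rows only, a choice made after the label check, the pluripotency list was lower with a cameraPR adjusted p of 3.9e-07 and the primed epiblast list, with 2 of its 4 members higher, with 0.0040.

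Other rows of the checked stretch rose at day 10. Apoc2, an apolipoprotein, had a log2 fold change of 4.93 (0.35), Hgf, hepatocyte growth factor, 4.83 (0.49) and Slc8a1, the sodium-calcium exchanger of cardiac muscle, 2.38 (0.13) in the authors' deposited table. Pcdh11x (2.15), Lrrn3 (1.92), Hoxa9 (1.78), Lox, a collagen cross-linking enzyme (1.19), Tal1, a factor of blood and endothelial precursors (0.94), and Fn1 (0.38) were higher in the authors' deposited table. Sox17 was lower at -0.37 (0.11) in the authors' deposited table. The lowest row was Gm21304 at -6.67 (0.54), followed by Fgf5, Mcf2 (-2.26), Otx2, Lrmp (-1.95) and Ephx2 (-1.91) in the authors' deposited table. Rpl22 (-0.65), Rpl37rt (-0.38), Gapdh (-0.34) and Mdm2 (-0.33) fell, and H2bc4 was at 0.11 in the authors' deposited table. Of 62 histone rows 20 rose, 10 fell and 32 were not called (20 and 11 adjusted over the list alone), and as a list they did not pass (median log2 fold change 0.06, cameraPR adjusted p = 0.20).

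Over all rows of day 10, 8369 of 17916 were called by DESeq2 in the authors' deposited table, 3917 higher and 4452 lower, and 1855 differed at least 2-fold, 1215 higher and 640 lower. In the checked stretch 330 of 670 rows were called, 158 higher and 172 lower. Rows with a base mean of at least 500 had a median log2 fold change of -0.11 at this day (-0.07, 0.00 and -0.01 at days 0, 2 and 4), and smaller changes are to be read against it. With the empirical null 1147 rows passed, 438 higher and 709 lower, and the calls of Hgf, Pcdh11x, Lrrn3, Lrmp, Lef1, Sox17, Tal1, Lox, Hoxa9, Brd8, Mdm2, H2bc4 and Rpl37rt ended.

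**Figure D2:**
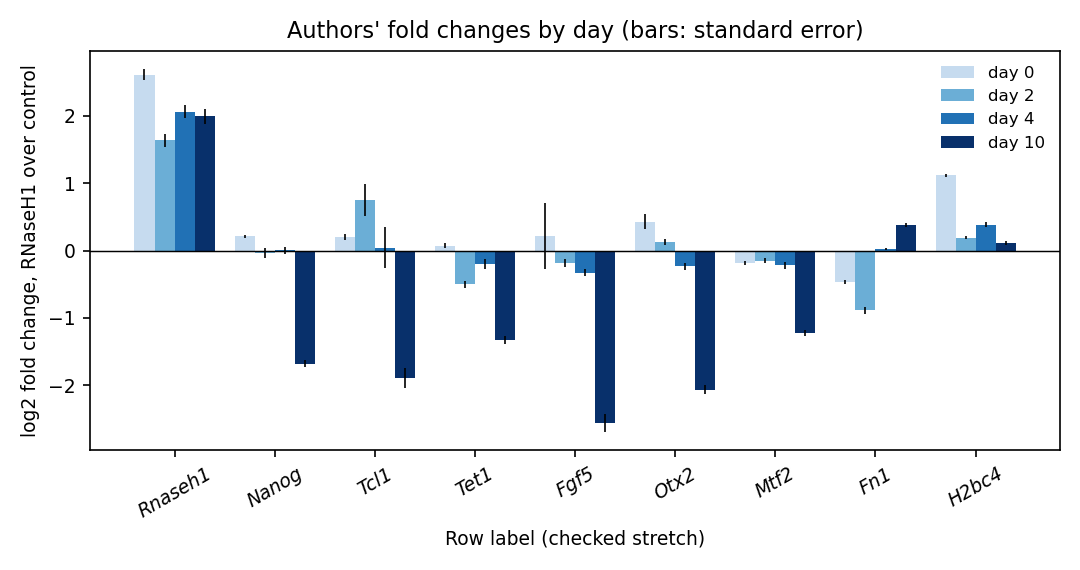
Log2 fold change of RNaseH1 over control (y axis) with its standard error (bars) for 9 row labels of the checked stretch (x axis), by day, from the authors' deposited tables. Rnaseh1 lies between 1.64 and 2.61 on all days, while Nanog, Tcl1, Tet1, Fgf5, Otx2 and Mtf2 are below -1 at day 10 alone. Tcl1 at days 2 and 4 and Fgf5 at day 0 have no adjusted p.

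Taken with their labels as deposited, 10 of the 92 tests of 23 lists by day passed. Besides the histones of days 0, 2 and 4, the ribosomal protein list was higher at day 0 (median log2 fold change 0.18, adjusted p = 2.3e-10) and lower at day 10 (-0.29, adjusted p = 9.7e-09). Of its 79 rows at day 0, 33 rose, 10 fell and 36 were not called (33 and 11 adjusted over the list alone), and of its 84 rows at day 10, 12 rose, 40 fell and 32 were not called, the same 12 and 40 adjusted over the list alone. On fold changes in place of the Wald statistic both ribosomal calls ended (adjusted p = 0.50 and 0.10). The 2-cell-like state list was lower at day 2 (adjusted p = 0.038), a call that ended with a correlation of 0.05 (adjusted p = 0.13), on ranks (0.38) and with a base mean of at least 50 (0.18). At day 10, R-loop processing without Rnaseh1 (0.013), proliferation (0.013) and glycolysis and hypoxia (0.032) were lower and mesenchyme and matrix (0.011) was higher, with adjusted p in parentheses. These 4 calls ended with a correlation of 0.05 (adjusted p = 0.10, 0.10, 0.17 and 0.10 in that order) and also on fold changes and on ranks.

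The other 82 tests did not pass, with adjusted p from 0.080 to 0.95. The 16 lists with no passed day were pluripotency, primed epiblast, primitive streak and early mesoderm, endoderm, neuroectoderm, cardiac muscle, endothelium and blood, trophoblast, Hox genes, developmental transcription factors with Polycomb-marked promoters, Polycomb subunits, Tip60-p400 subunits, p53 targets, interferon response, immediate early and imprinted genes. All these tests rest mostly on labels outside the checked stretch, so, apart from the histones, whose labels often neighbour each other, neither passes nor failures can be read as a statement on the genes. With a correlation of 0.05, 5 calls held, those of the histones at days 0, 2 and 4 and of the ribosomal proteins at days 0 and 10. On fold changes 4 of the 10 calls held, those of the histones and the 2-cell-like state. On ranks the 5 calls of the histones and ribosomal proteins held. Hox genes passed at day 10 on fold changes (3.5e-13) and ranks (0.0014), and endothelium and blood on fold changes (0.00016), all higher.

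**Figure D3:**
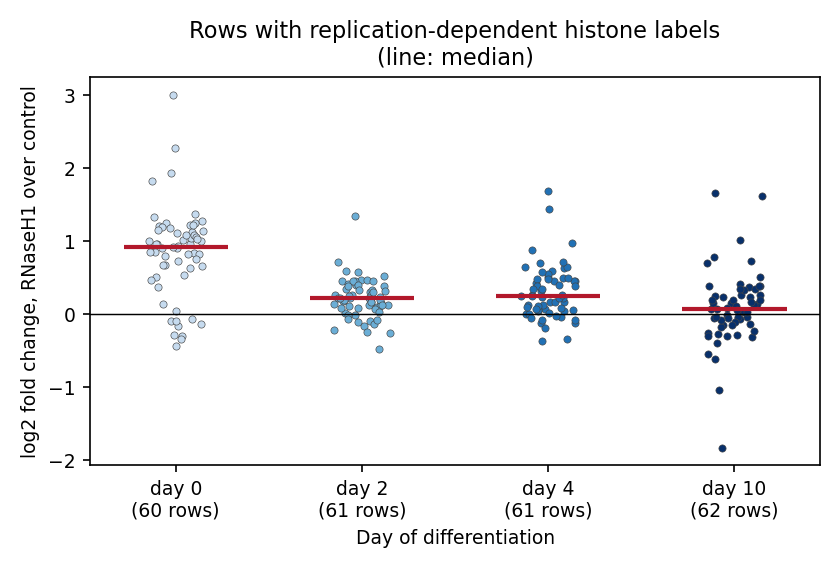
Log2 fold change of RNaseH1 over control (y axis) of each row with a replication-dependent histone label (points) by day (x axis), from the authors' deposited tables, with the median as a line. The median goes from 0.92 at day 0 to 0.22, 0.24 and 0.06 at days 2, 4 and 10.

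Judged by the authors' standard errors, the effect of RNaseH1 differed between days. At base means of 1000 to 5000 those errors imply a median dispersion of only 0.00094 to 0.00104 at days 0, 2, 4 and 10. Whether such small errors include variation between cultures is not known. The adjusted p below hold only if they do, and the differences are better read by their size. Nanog went from 0.21 at day 0 to -1.68 at day 10 in the authors' deposited tables, a difference of -1.89 (standard error 0.06, adjusted p = 7.3e-185), and Otx2 from 0.43 to -2.06, a difference of -2.49 (0.13, adjusted p = 5.8e-79). H2bc4 lost most of its rise by day 2, with a difference of -0.93 (0.03, adjusted p = 1.3e-213). Fn1 turned from -0.47 at day 0 to 0.38 at day 10 in the authors' deposited tables, a difference of 0.84 (0.04, adjusted p = 2.4e-91). Calu, a calcium-binding protein of the secretory pathway, differed by 0.86 (0.05, adjusted p = 1.5e-65) over the same days. Ephx2 was lower at day 0 by more than at day 2, with a difference of 1.45 (0.12, adjusted p = 1.4e-29).

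By row, 3399 of 15577 effects differed between days 2 and 0 (1775 higher and 1624 lower at the later day), 3444 of 15537 between days 4 and 0 (1748 and 1696), 6254 of 15951 between days 10 and 0 (2402 and 3852) and 5719 of 16386 between days 10 and 4 (2383 and 3336). Rows with a base mean of at least 50 called on both days with opposite signs numbered 360, 394, 1396 and 544 in these pairs, against 574, 694, 1535 and 858 by chance. With the empirical null 835, 742, 808 and 761 rows differed, and the share higher at the later day went from 52.2% to 46.6% for days 2 and 0, from 50.8% to 49.9% for days 4 and 0, from 38.4% to 23.5% for days 10 and 0 and from 41.7% to 25.4% for days 10 and 4. Shrinkage may differ by day and so alter the differences by row and the 2-fold counts of each day. The most that the largest standard errors allow at base means of 50 to 200 is a median of 19.7% at day 0. It is 36.4%, 39.6% and 10.3% at days 2, 4 and 10. Of the 92 list differences 11 passed, led by the histones between days 2 and 0 (median difference -0.64, adjusted p = 3.3e-72), and 8 of these passed with a correlation of 0.05, 9 on ranks and 4 on fold changes.

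Days 2 and 4 resembled each other most. Across rows, which are not independent replicates, Pearson's r of the log2 fold changes was 0.58 for days 2 and 4, 0.33 for days 0 and 4, 0.32 for days 0 and 2, 0.23 for days 4 and 10, 0.15 for days 0 and 10 and 0.084 for days 2 and 10. Rows higher at both days 2 and 4 numbered 633 against 158 by chance (Fisher's exact test, two-sided, adjusted over 12 overlaps, p = 1.8e-301), and 610 against 170 were lower at both (8.1e-253). For days 0 and 10, 508 rows were higher at both against 529 by chance (adjusted p = 0.25), and 1631 were lower at both against 1077 (adjusted p = 4.2e-133). In the other 4 pairs more rows were shared than by chance in each direction, with adjusted p of 0.00025 or less.

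Levels averaged over control and RNaseH1 libraries changed over the course. Nanog held 565 per 1000000 of the summed base means at day 0 and 82.8, 136 and 119 at days 2, 4 and 10 in the authors' deposited tables. Fgf5 held 0.473 per 1000000 at day 0, 106 and 143 at days 2 and 4 and 29.7 at day 10 in the authors' deposited tables. Sox17 held 0.378, 0.871, 60.3 and 28.4 per 1000000 at the 4 days, and Tcl1 170, 5.63, 0.469 and 18.5, in the authors' deposited tables. The tables were normalised separately and these levels were not tested.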

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

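The rows listed first differed in their RNaseH1 effect between 2 days by the z test on the authors' deposited tables, and the lists did so by cameraPR on that z. The tests of a 1-row displacement, of the gene symbols, of a shift of scale, of the choice of members, of the standard errors and of shrinkage were chosen only after the result was seen. The other tests were set before their values were known, although the fold changes of Rnaseh1, but not its rank, had been seen.

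By row, 3399 effects differed between days 2 and 0, 3444 between days 4 and 0, 6254 between days 10 and 0 and 5719 between days 10 and 4. Differences below are the log2 fold change of the later day minus that of the earlier one, for the rows of the checked stretch with the highest and lowest z.

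Between days 2 and 0 the effect was higher for Pkm by 0.52, Ephx2 by 1.45, Mcf2 by 1.05, Calu by 0.67 and Arhgef3 by 1.28. It was lower for H2bc4 (-0.93), Chd7 (-1.47), Adarb2 (-0.37), Eef1d (-0.52) and Ncor2 (-1.999). Between days 4 and 0 it was higher for Pkm by 0.58, Gapdh by 0.20, Fn1 by 0.49, Calu by 0.59 and Ephx2 by 1.64. It was lower for H2bc4 (-0.73), Gm10408 (-3.52), Eef1d (-0.58), Chd7 (-1.03) and Rpl31-ps12 (-0.37).

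Between days 10 and 0 the effect was higher for Fn1 by 0.84, Calu by 0.86, Prnp by 0.70, Txndc5 by 0.90 and Vasp by 0.75, and lower for Adarb2 (-2.09), H2bc4 (-1.01), Nanog (-1.89), Rpl22 (-0.84) and Otx2 (-2.49). Between days 10 and 4 it was higher for Prnp by 0.61, Slc8a1 by 2.57, Fn1 by 0.36, Slc4a2 by 1.05 and Jund by 0.64, and lower for Pkm (-0.76), Adarb2 (-1.88), Gapdh (-0.34), Cad (-1.26) and Nanog (-1.68). All 40 of these passed with the empirical null as well, but it rescales the same z by which they were picked and is no separate support. The levels of the row labelled Adarb2 are out of keeping with its name, so its differences may belong to another gene.

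Of the lists, the replication-dependent histones had median differences of -0.64, -0.59 and -0.83 for days 2, 4 and 10 against day 0 and of -0.19 for day 10 against day 4. The ribosomal protein labels had -0.24, -0.24, -0.61 and -0.35 in the same order. Glycolysis and hypoxia differed by 0.20 between days 4 and 0 and by -0.22 between days 10 and 4, and proliferation by -0.43 between days 10 and 4. With a correlation of 0.05 the adjusted p was 0.077 for glycolysis between days 4 and 0, 0.051 for proliferation and 0.27 for the histones between days 10 and 4, and the other 8 held. On fold changes 4 of the 11 held, the histones of days 2, 4 and 10 and the ribosomal proteins of day 10 against day 0, and the other 7 had adjusted p from 0.11 to 0.42. Under the displaced reading the histone difference between days 10 and 4 had an adjusted p of 0.087.

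The first pattern is that values do not belong to their labels. For the ribosomal protein labels of the middle block the median base mean 1 row below was 21.3 times that on the own row, which is consistent with a label column displaced by 1 row there. Wrong symbols in the table of names are argued against, since 98.1% of 17871 labels had the same symbol in a second annotation. A displacement across the checked stretch as well is argued against by the row labelled Rnaseh1, which stood at rank 1 of 10219 rows, although this speaks for its neighbourhood more than for every row. Where the displacement arose stays open, and no biological explanation was tested.

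The second pattern is that the 3 pluripotency rows were lower with RNaseH1 than in controls at day 10. A shift of scale common to all rows would leave no gap between abundant rows and the pluripotency and primed epiblast rows. Their medians differed by 1.57 log2 units. Size-factor normalisation centres the abundant rows beforehand, so this gap largely restates the low values and is no separate evidence. A chance choice of pluripotency members by the checked stretch is argued against by the displaced reading of the rows outside it, in which that list was also lower (adjusted p = 9.6e-33), while the primed epiblast list did not pass there (median -0.38, adjusted p = 0.44), so for Fgf5 and Otx2 such a choice stays open. Whether RNaseH1 cells were further along the course the controls take cannot be told apart. The correlation across rows was 0.12 with the controls' change from day 4 to day 10, between the bounds set. It was 0.53 with their change from day 0, a value seen only afterwards. Both correlations share the day 10 controls with opposite sign. Noise in those controls would push them in the negative direction, by an unknown amount, so it does not account for the positive values. Nanog, Tet1 and Tcl1 had base means of 8185, 3663 and 2458 at day 0, 1874, 1071 and 6.46 at day 4 and 1677, 1454 and 262 at day 10. With the fold changes, this puts their control levels at day 10 above those at day 4 and below those at day 0. The lower values of these 3 rows thus run against the controls' change from day 4 and with that from day 0. These levels were normalised separately by day and not tested. An effect of RNaseH1 itself and a difference between the cultures also stay open.

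The third pattern is that more rows were called at day 10 than at day 0 and their fold changes spread wider, although at base means of 5000 and above 90.9% were called against 92.2% and 5.84% differed at least 2-fold against 6.13%, with an SD of 0.57 against 0.47. Smaller errors are argued against, since at base means of 1000 to 5000 the median standard error was 0.98 times that of day 0, which met neither bound set for it, and at 50 to 200 it was 0.225 against 0.220 while 43.8% of rows were called against 23.6%, a comparison chosen with the values in view. Fold changes shrunken more at day 0 are argued against at base means of 1000 to 5000, where the largest standard errors (0.49 and 0.70 in the authors' deposited tables) allow a normal prior to shrink by a median of 1.39% at most, and the SD at day 10 was 1.32 times that of day 0 with this undone, and 1.22 to 1.59 times in the other classes of base mean 50 and above, while rows of base mean under 50 stay open. Errors that leave out variation between cultures cannot be told apart. At base means of 1000 to 5000 the errors imply a median dispersion of 0.00104 at day 0 and 0.00096 at day 10. Day 10 had 5.68 times the called rows of day 0 with a dispersion of 0.04 added, above the bound set, but that size was assumed. With the empirical null, which takes the spread from the statistics themselves, it had 1.06 times. That null divides by each day's own width (2.65 at day 0 and 3.70 at day 10), so it would also remove a wider spread of true effects. A larger effect of RNaseH1 after differentiation and a difference between the day 10 cultures stay open as well.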

How the results depend on the processing

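No paired analysis was possible because the tables used here hold no values per library. For the same reason the replicate block, the counts without each replicate and the edgeR and DESeq2 normalizations were planned but not run. The added dispersions, the label-checked rows, the displaced reading and the list differences other than at a base mean of at least 50 were chosen after seeing the data. Depth is unknown, so what it limits cannot be said beyond the authors' standard errors. The cause of the changes below was not tested, except that added dispersion and a minimum fold remove calls by construction.

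Counts of called rows stayed within 1.5 times at adjusted p under 0.01 or 0.1 and with other filters on base mean. At days 0, 2, 4 and 10 they were 521, 19, 3 and 1855 at 2-fold or more, 1079, 839, 641 and 1147 with the empirical null, 2196, 145, 24 and 4954 with a dispersion of 0.01 added and 276, 7, 2 and 1568 with 0.04. Differences of days 2, 4 and 10 from day 0 and of day 10 from day 4 fell to 835, 742, 808 and 761 rows with the empirical null, 453, 378, 2838 and 1968 with a dispersion of 0.01 and 31, 20, 411 and 345 with 0.04. Of 88 named calls 51 passed with the empirical null. Agreement r with a base mean of at least 10 was 0.269 for days 0 and 2, 0.301 for 0 and 4, 0.176 for 0 and 10, 0.47 for 2 and 4 and 0.174 for 4 and 10. With at least 200 it was 0.359 for days 0 and 4, 0.639 for 2 and 4, 0.114 for 2 and 10 and 0.288 for 4 and 10. Scaled by the median ratio to day 0, the log2 level over day 0 was -2.17 and -2.42 for Nanog and 8.12 and 5.80 for Fgf5 at days 4 and 10, against -2.06, -2.25, 8.24 and 5.97. In place of 10 list tests, 6 passed on fold changes (4 of the 10), 6 on ranks (5 of the 10), 5 with a correlation of 0.05 (all among the 10), 7 with a base mean of at least 50 (all among the 10, without the 2-cell-like state, glycolysis and hypoxia and R-loop processing), 2 on label-checked rows only (none of the 10) and 30 under the displaced reading (8 of the 10). In place of 11 list differences, 31 passed under it (10 of the 11), 10 on fold changes (4 of the 11), 10 on ranks (9 of the 11), 8 with a correlation of 0.05, 11 with a base mean of at least 10 and 12 with at least 50. Another 36 main values and counts moved by less than the spread or 1.5 times allowed for them, such as 4528 in place of 5690 at day 0 and 1825 in place of 2726 at day 4 at adjusted p under 0.01. The balance of directions was less stable. At day 0 it turned from 2691 higher and 2999 lower to 352 and 169 at 2-fold, 595 and 484 with the empirical null, 1275 and 921 with a dispersion of 0.01 and 191 and 85 with 0.04. At day 2 it turned to 5 and 14, 417 and 422, 59 and 86 and 2 and 5 in the same order, and at day 4 to 3 and 0, 325 and 316, 19 and 5 and 2 and 0. At day 10 it turned to 1215 and 640 at 2-fold and 915 and 653 with 0.04, but not with the empirical null or 0.01. The share of differences higher at the later day turned from 52.2% to 46.6%, 35.3% and 16.1% for days 2 and 0 with the empirical null, 0.01 and 0.04, and from 50.8% to 49.9%, 46.8% and 35.0% for days 4 and 0. For days 10 and 4 it turned from 41.7% to 54.2% with 0.04, and for days 10 and 0 it stayed below an even split in these 3 settings. For single genes and lists, 146 values kept their side of the threshold and 71 lost it, all with the same direction.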

Other observations

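A hypothesis concerns rows outside the checked stretch. If each value of the middle block belongs to the label 1 row above it, as the 21.3-fold rise of ribosomal protein labels suggests, the lists can be read again there, without naming genes. This reading was chosen after the values had been seen, and it was not planned. At day 10 the pluripotency list, with 14 members outside the checked stretch, then had a median log2 fold change of -1.73 (cameraPR adjusted p = 9.6e-33), and proliferation was lower as well (-0.60, adjusted p = 6.0e-08). Lists of differentiated cells were higher, namely endoderm (0.55, adjusted p = 4.8e-21), mesenchyme and matrix (0.85, 4.9e-20), endothelium and blood (2.40, 1.2e-06), trophoblast (0.79, 9.1e-07), primitive streak and early mesoderm (0.50, 0.0013) and cardiac muscle (1.50, 0.0051). The rise was not limited to these, since imprinted genes (4 members, 1.99, adjusted p = 1.6e-44), immediate early genes (0.51, 0.0013) and developmental transcription factors with Polycomb-marked promoters (0.38, 0.033) were also higher. The call of these transcription factors ended with a correlation of 0.05 over all rows read (adjusted p = 0.15). R-loop processing was lower (-0.49, 0.014). Hox genes did not pass (1.42, adjusted p = 0.071). Primed epiblast (9 members, -0.38, adjusted p = 0.44) and neuroectoderm (-0.26, adjusted p = 0.84) did not pass.

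Also outside the checked stretch, the ribosomal protein list was higher at day 0 (median 0.44, adjusted p = 2.6e-171) and lower at day 10 (-0.54, adjusted p = 2.6e-97). With the rows of the checked stretch included, 30 of the 92 list tests by day passed in place of 10. These values may show that lists carry more signal once labels and rows are brought together, but the test does not restore any single row, and the lists overlap in what they measure. With a correlation of 0.05 the day 10 adjusted p over all rows read was 1.8e-24 for pluripotency, 8.7e-13 for endoderm and 2.2e-13 for mesenchyme and matrix. It was weaker for primitive streak and early mesoderm (0.014), immediate early genes (0.014), cardiac muscle (0.024) and R-loop processing (0.033). The developmental transcription factors did not pass, as given above.

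Controls' own change from day 0 to day 10, derived from the base mean and the fold change, was set against the RNaseH1 effect at day 10. The 1616 rows that rose at least 2-fold in controls had a median log2 fold change of 0.29 with RNaseH1, and the 471 that fell at least 2-fold had -0.61. For the controls' change from day 4 to day 10 the medians were 0.18 for 773 rows that rose and 0.06 for 226 that fell. Both quantities use the day 10 controls with opposite sign. Noise in those controls would lower the median of rows that rose and raise that of rows that fell, by an unknown amount. This comparison was chosen after the values were seen.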
